A study of Mus musculus with 4 samples.

How the data were processed

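Ring1B occupancy was measured in wild-type and homozygous Phc2 L307R mouse embryonic fibroblasts on 2-colour promoter arrays. Per the labels, immunoprecipitated and input DNA were amplified with a T7 RNA polymerase step, with input in Cy3 and the Ring1B immunoprecipitate in Cy5. No dye swap was made on these 4 arrays. The numbers in the sample titles name array designs that share 0 probes, so they are no replicates, and each promoter has 1 array per genotype. The design fixed for this case was used: fixed rules of size, with no p-values. Genotype was taken from the labels.

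The deposited scanner files hold spot intensity values, which per the file headers were quantified with Agilent Feature Extraction 10.7.3.1, with background subtraction based on negative controls, spatial and multiplicative detrending and linear dye normalization. They also give the log10 ratio of Cy5 over Cy3 for each spot, per the file headers. The deposited value tables are on the log10 scale too, as found by setting them against the scanner ratios, with column medians of -0.056 and -0.0342 on design 1 and -0.0615 and -0.0393 on design 2 for wild type and Phc2 L307R. The Phc2 L307R tables equal the scanner ratios minus a constant at 99.9% of probes (within 0.001 plus 0.51% of the value), whereas the array or processing behind the wild-type tables stays unknown. The genome build of the probe positions is not given in the sources used here. Only 9.74% of 16132 gene names with a position in GRCm38 lay within 10 kb of it, although 99.9% lay on the same chromosome, so no reference coordinates are used.

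The scanner ratios were converted to log2 and centred on the median of each array, after control spots and spots with outlier flags were left out. Saturated spots were kept. Of 474380 probes, 462748 carried a gene name in the files. Of 18354 names, 13168 matched a current symbol, 3186 an older synonym and 1436 a pair of genes that share a promoter; 564 were unmatched and keep the name of the files. Phc2, Cdkn2b and some Hox genes have no named probes and were not analysed here. Some other promoters enter the counts and list medians but are not reported here singly.

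For each promoter, the window of 3 neighbouring probes within 2000 bp with the highest mean over both genotypes was used, which left 17652 promoters. A promoter was called bound at a window mean of at least 1 (log2). The same cut-off with the sign turned, applied to the lowest window, gave a background count. A bound promoter was called lower or higher in Phc2 L307R (fell or rose) if its window differed by at least 1 (log2), with all 3 probes on the same side. The probe noise, as the SD from successive probes, was 0.399 and 0.315 in wild type and 0.427 and 0.408 in Phc2 L307R on designs 1 and 2. The number of arrays limits the precision.

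The 39 gene lists were fixed before the data were examined, as were the rules, the settings and the rule for named genes. Each list is described by its median and by the percentile of the median difference among 10000 random lists, with each member drawn from the 100 promoters nearest in mean enrichment. A percentile below 2.5 or above 97.5 is outside the central 95%; it describes these arrays only. Named genes are the 10 largest falls, the 10 largest rises, the 10 highest wild-type promoters, up to 2 bound members of each list with the lowest and up to 2 with the highest differences, and Cdkn2a, Cdkn2b, Phc2 and Rnf2; the text gives examples of the list members.

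The steps were tested on simulated data with probe noise as the only error, with 25 of 17652 promoters changed by each of 8 sizes. Of these, 25 were recovered at -2, 24 at -1.5, 11 at -1, 0 at -0.5, 3 at 0.5, 15 at 1, 24 at 1.5 and 25 at 2 (log2), and 21 of 8756 unchanged bound promoters were called. With no list changed, 3 of 39 lists lay outside the central 95%, and a list shifted by 0.8 reached the percentile 100.

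The alternatives were normexp background correction on the mean and background signals (offset 50), loess within arrays, scaling of arrays to the same median absolute deviation (called the same spread), the value tables, a filter on dim probes, windows of 5 probes or chosen in a single genotype, the mean over all probes of a promoter, a bound cut-off of 1.5, each distinct window counted once, single array designs, a size rule of 1.5-fold and random lists without matching. The spread shared by neighbouring probes was the root of the covariance of successive probes of a promoter, with an interval from leaving out each chromosome in turn, and was added after seeing the data. A bound cut-off of 3 and the comparison against both sets of wild-type values were added after seeing the data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1; figures were drawn with matplotlib 3.10.9.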

Results

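Ring1B, the E3 ubiquitin ligase of Polycomb repressive complex 1 (PRC1), was mapped on mouse promoters by chromatin immunoprecipitation and hybridisation to oligonucleotide arrays (ChIP-on-chip). The cells were mouse embryonic fibroblasts, primary cells grown from embryos of day 12.5 and used at passage 2, either wild type or homozygous for Phc2 L307R. Phc2 is a PRC1 subunit whose SAM domain forms polymers, and the study's title sets SAM domain polymerisation beside PRC1 clustering and silencing, so the comparison asks how Ring1B occupancy of promoters differs in cells with the altered Phc2. There were 4 arrays, 1 per genotype on each of 2 array designs that shared 0 probes, with 237195 probes on design 1 and 237185 on design 2. Each promoter was thus measured once per genotype, no error between cultures can be given, and no p-value is reported. The error given beside some genes is the SD over the 3 neighbouring probes of the window. Where no SD is printed, it may still be large. The single-nucleotide change in Phc2 cannot be read from these arrays, and no probe here carries the gene name Phc2, so the genotype rests on the labels. The wild-type arrays were scanned on another day than the Phc2 L307R arrays, so scan day, any difference in DNA preparation that went with it, and genotype cannot be told apart.

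Immunoprecipitate signal was well above background at 97.9% and 99.7% of probes on the wild-type arrays and at 99.1% on both Phc2 L307R arrays. Input signal was well above background at 85.7% and 86.7% of probes in wild type and at 75.0% and 76.3% in Phc2 L307R. The wild-type values exist in a pair of versions that differ. For Phc2 L307R the deposited value tables equalled the scanner ratios minus a constant at 99.9% of probes, whereas the wild-type tables correlated with the wild-type scanner ratios at only 0.854 on design 1 and 0.890 on design 2. Values below come from the scanner files. Value-table results stand beside many of them but not all, and of 118 genes followed through the settings 29 had the opposite sign in the value tables. Both comparisons use the same Phc2 L307R arrays, so the value tables are no independent repeat.

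Most of the 10 promoters with the highest enrichment in wild-type fibroblasts belonged to developmental transcription factor genes, although Igf2bp3 and D830007B15Rik did not. Nkx2-3, a homeobox gene of gut and spleen development, stood highest at a log2 immunoprecipitate/input ratio of 6.09 (SD over its probes 0.17). It was followed by the homeobox gene Cart1 at 6.01, the cardiac and endodermal factor Gata4 at 6.00, the ovarian factor Foxl2 at 5.96, D830007B15Rik (now Shisa3) at 5.93, the pluripotency and neural factor Sox2 at 5.89, Tlx3 at 5.85, Igf2bp3 at 5.82, Lhx8 at 5.81 and Sall3 at 5.75. All 10 were higher still in the wild-type value tables, from 6.39 for Tlx3 to 7.19 for Sox2 and D830007B15Rik.

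Among the 39 gene lists, LIM homeobox genes had the highest wild-type median, 4.24 over 10 promoters, followed by Nkx genes at 4.05 over 12 and forebrain and paired-like homeobox genes at 3.79 over 47. Gata genes stood at 3.72, Pax genes at 3.64, Dlx and Msx genes at 3.61 and the HoxB cluster at 3.53. Blood cell genes had the lowest median, 0.08, followed by olfactory receptor genes at 0.13, liver genes at 0.17, skeletal and heart muscle genes at 0.21, germline genes at 0.36 and endothelial genes at 0.42. Housekeeping genes at 1.64 and ribosomal protein genes at 1.22 lay between these groups, with 20 of 24 and 59 of 75 promoters at or above the cut-off of 1, so promoters of broadly expressed genes also passed it. At a cut-off of 1, 8004 of 17652 promoters counted as bound in wild type, against 393 whose lowest window reached -1. At a cut-off of 3, chosen after seeing the data, 278 were bound and 0 reached -3.

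**Figure D1:**
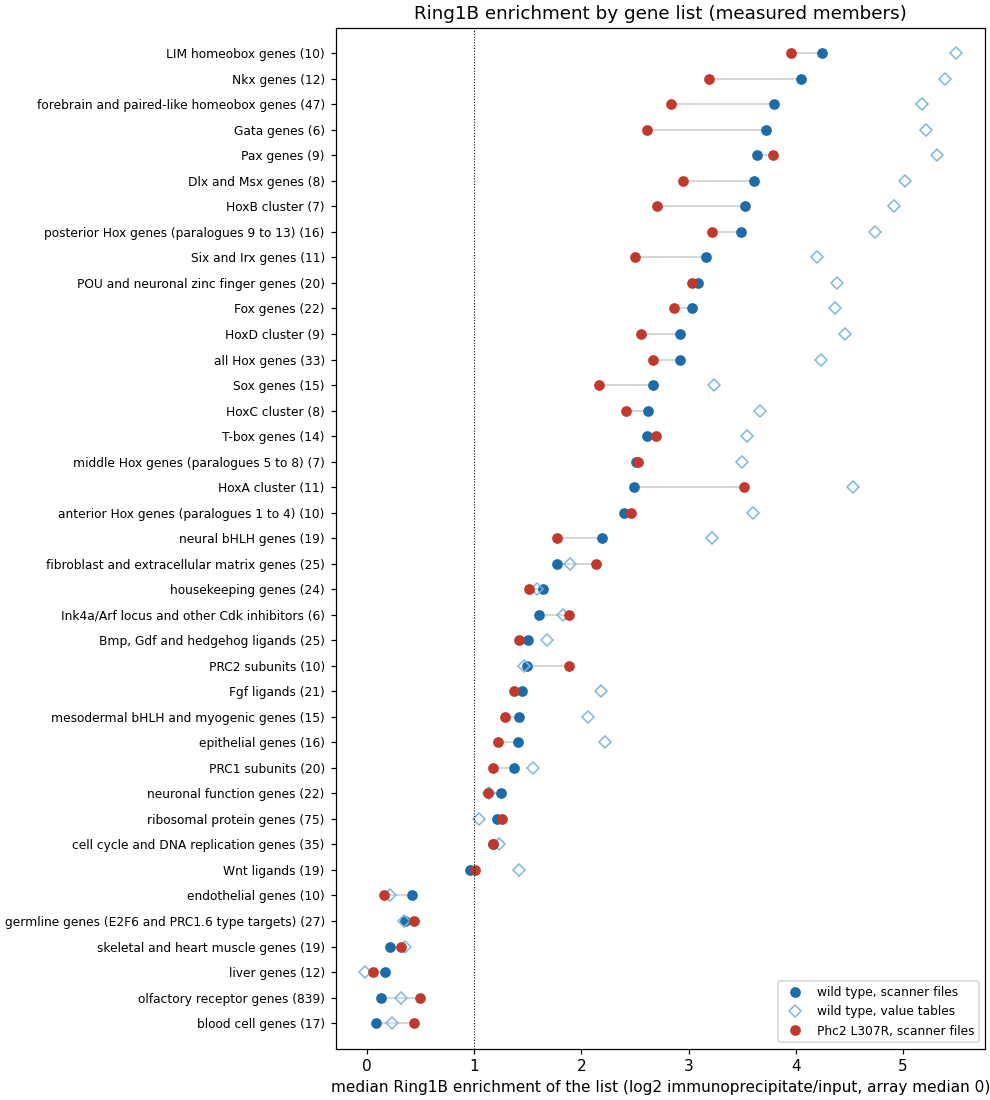
Median Ring1B enrichment (log2 immunoprecipitate/input, array median 0) of each gene list in wild type from the scanner files (blue circles), in wild type from the value tables (light diamonds) and in Phc2 L307R (red circles), with the number of measured promoters in brackets and the cut-off of 1 dotted. Homeobox and other developmental lists reach 4.24 in wild type. In the scanner values the HoxA cluster is the list with the widest gap in favour of Phc2 L307R (2.49 against 3.52). Its wild-type median in the value tables is 4.54. The wild-type value tables lie above the wild-type scanner values at strongly occupied lists.

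In Phc2 L307R fibroblasts, forebrain and paired-like homeobox genes and Gata genes held less Ring1B relative to random lists of like enrichment (percentiles 0.2 and 0.55) and HoxA promoters more (100), while most other developmental lists lay inside the central range. The calls on the forebrain and paired-like genes and on the Gata genes were lost under some settings. The HoxA median changed sign, from 0.79 in the scanner values to -0.37 in the value tables. Of the 8004 promoters bound in wild type, 5944 were bound in Phc2 L307R, or 74.3% (Wilson 95% interval 73.3% to 75.2%, counting error only), but this share was 48.0% after normexp background correction. Between the 2 sets of wild-type values, with windows chosen on both, the same share was also short of complete, at 84.0% (6780 of 8075). Another 982 promoters were bound in Phc2 L307R only. In all, 6926 promoters were bound in Phc2 L307R, against 1357 whose lowest window reached -1, more than the 393 in wild type. By the size rule, a 2-fold difference with all 3 probes on the same side, 271 bound promoters were lower in Phc2 L307R and 148 were higher. Among 8666 unbound promoters the same rule took 15 as lower and 47 as higher. Both values lie below 1 there, which leaves little room for a difference of 1, so these counts do not measure the noise at bound promoters. The median difference over 8986 bound promoters was -0.14, and 61.8% of them lay below 0. Since each array was centred on its own median, differences are relative to that median. A change shared by all promoters would not show. The median difference was close on both array designs. The values were -0.17 on array design 1 and -0.11 on array design 2.

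With the value tables in place of the scanner values, 731 promoters were lower and 52 higher. The 2 sets of wild-type values differed from each other by the same rule at 524 promoters in the upward direction and 43 in the downward direction, so differences of this size also stood between 2 sets of values labelled as wild type. Lower in Phc2 L307R against both sets were 103 promoters, and higher against both were 27. Unchanged promoters simulated with the shared Phc2 L307R arrays gave a mean of 0.25 and 1.75, and independent lists would share 16.6 and 0.903. The simulation held probe noise only, with no difference between cultures, preparations or scan days, and the figure for independent lists ignores the shared arrays. Neither can therefore tell whether 103 and 27 exceed what differences between arrays would give. Scaling also moved the balance of lower against higher promoters, to 418 against 99 after equalising the spread of the arrays and to 198 against 11 after normexp background correction, with median differences of -0.27 and -0.34. The equalised spread (the median absolute deviation) includes probe noise and was 1.05 and 1.11 times as wide in Phc2 L307R, so this scaling lowers high Phc2 L307R values relative to wild type. The spread shared by neighbouring probes, another measure, was 0.933 and 0.941 of that in wild type. The SD of the ratios, which also includes noise, was 0.804 in Phc2 L307R against 0.816 on design 1, and 0.811 against 0.797 on design 2. How much of the wider equalised spread is noise was not tested. Mitochondrial probes, which come from another genome than the promoters, had a median log2 ratio of -1.12 in wild type and -4.19 in Phc2 L307R over 47 probes, all on array design 2, and -0.40 in the wild-type value table.

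At the promoters that held most Ring1B, those at or above 3 in either genotype, 59 of 340 were lower in Phc2 L307R and 13 were higher, and the median difference was -0.30. The value tables gave 422 lower and 1 higher of 572, with a median of -1.51, whereas loess within arrays gave 38 lower and 24 higher with a median of -0.05. The median was -0.66 with arrays scaled to the same spread (111 lower, 3 higher), a scaling that itself lowers high Phc2 L307R values relative to wild type. After normexp the median was -0.91 (77 and 1), and with only probes well above background it was -0.47 (61 and 3). With the window highest in wild type it was -0.53 (77 and 4), and with the window highest in Phc2 L307R -0.11 (31 and 18). The wild-type value tables exceeded the wild-type scanner values by a median of 1.17 at such promoters.

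**Figure D2:**
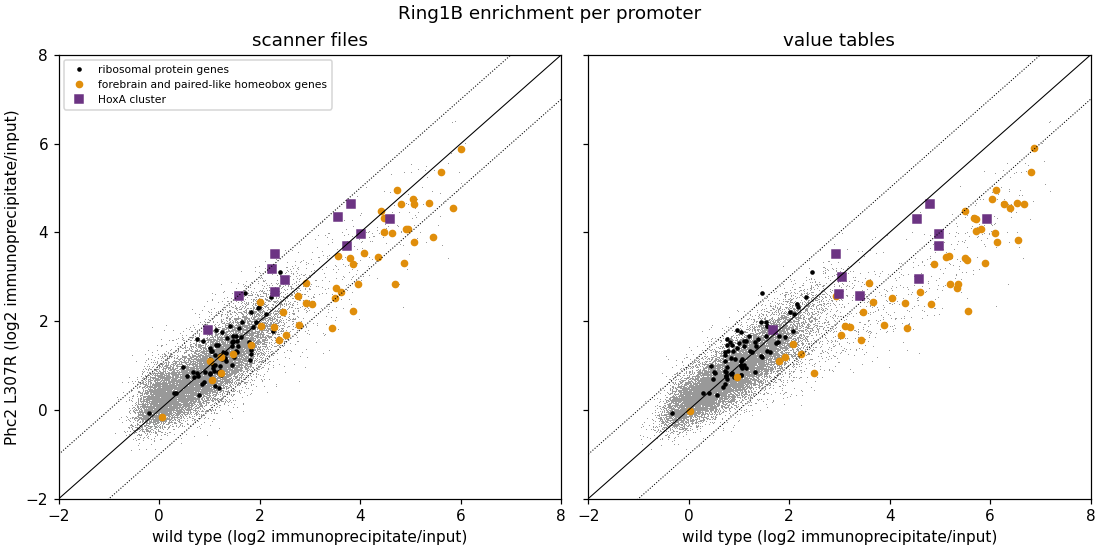
Ring1B enrichment of each promoter (grey points) in wild type (horizontal axis) and Phc2 L307R (vertical axis), log2 immunoprecipitate/input, from the scanner files (left) and the value tables (right); the solid line marks equal values and the dotted lines a 2-fold difference. Forebrain and paired-like homeobox genes (orange) have a median difference of -0.45 on the left and -1.66 on the right, HoxA cluster promoters (purple) 0.79 and -0.37, and ribosomal protein genes (black) 0.03 and 0.16.

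The largest fall was at Six2, a homeobox gene that maintains kidney progenitors. Its window on chromosome 17 (85600304 to 85600699, genome build not given in the sources used here) went from 4.85 in wild type to 2.31 in Phc2 L307R, a difference of -2.54 (SD over the 3 probes 0.13), and -3.81 in the value tables. Slc32a1, the vesicular GABA transporter gene, fell by 2.35 (SD 0.69) from 5.74 at chromosome 2 (158303782 to 158304238), and by 3.27 in the value tables. The homeobox genes Cutl2 (now Cux2, difference -2.06), Nkx6-2 (-1.97), Dmbx1 (-1.94) and Barhl1 (-1.86) were among the 10 largest falls. The others were Adcy5, an adenylyl cyclase gene (-1.99), the shared promoter of Gamt and Dazap1 (-2.16), Ralgps2 (-1.95, with an SD of 1.52 over its probes) and Slc27a2, a fatty acid transporter gene (-1.95). All 10 also met the rule for a fall in the value tables. These hold the same Phc2 L307R arrays, and 422 of 572 promoters at or above 3 met that rule there, so this is no independent repeat.

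The largest rises were mostly at promoters below the bound cut-off in wild type. Olfr969, an olfactory receptor gene, went from -0.15 to 1.85, a difference of 2.00 (SD 0.14). Tbx6, a T-box gene of the paraxial mesoderm, went from -0.54 to 1.23, a difference of 1.76 (SD 1.11). Ankrd1 differed by 1.76, Olfr456 by 1.70, Tbc1d12 by 1.59, Olfr957 by 1.58, Sulf1 by 1.56, Slc7a12 by 1.55, Gimap4 by 1.55 (SD 0.99) and Sez6l by 1.54. Olfr969, Tbx6, Olfr456, Slc7a12, Gimap4 and Sez6l also met the rule in the value tables, and the differences of the other 4 there lay between 0.40 and 0.92. The call was lost with a change of sign for Tbx6, Sulf1 and Tbc1d12 when only probes well above background in both channels were kept (-0.31, -0.21 and -0.06), and for Tbx6 and Sulf1 also after normexp (-0.0546 and -0.17). With the window highest in wild type, a choice that favours wild type, it was lost with a change of sign for Sulf1 (-0.42), Olfr456 (-0.20), Tbx6 (-0.17), Tbc1d12 (-0.11) and Gimap4 (-0.0024). Olfactory receptor genes as a whole, silent in fibroblasts and weakly occupied, had a median difference of 0.33 over 839 promoters, with 0 lower and 21 higher. It was 0.19 in the value tables with 9 higher, 0.12 after normexp, and 0.0552 or 0.56 with the window highest in wild type or in Phc2 L307R, at the percentile 100 each time. All these settings use the same Phc2 L307R arrays. The wild-type value tables also exceeded the wild-type scanner values at this list, by a median of 0.15 at the percentile 100. That percentile thus arose between 2 sets labelled as wild type too.

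The 4 Hox clusters are classical Polycomb targets that set position along the body axis. The HoxB median was -0.77 over 7 promoters, all of them below 0, which lay inside the central range of random lists of like enrichment (percentile 3.08). Of these, Hoxb6 (-1.46), Hoxb3 (-1.12) and Hoxb13 (-1.06) met the rule for a fall, although Hoxb6 stood at 0.55 in the window that was highest in Phc2 L307R. The HoxA median was 0.79 over 11 promoters, with 3 below 0, but in the value tables it was -0.37, and all 4 cluster medians lay below 0 there. Hoxa4 (0.99, SD 0.33), Hoxa5 (0.93, SD 1.31), Hoxa10 (0.83) and Hoxa9 (0.79) did not reach the rule, while Hoxa11 (-0.07) and the neighbouring Evx1 (-0.28) lay near 0.

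Against random lists of promoters with like enrichment, the HoxA median stood at the percentile 100 and, in the value tables, at 99.8, where such lists had a median between -1.92 and -0.83. Promoters of a Hox cluster lie side by side, whereas members of random lists came from any position, so these percentiles may overstate how unusual a cluster is. The HoxB median stood inside the central range in the value tables too (7.57, median -2.02), but below it after normexp (2.35, median -1.17), with arrays scaled to the same spread (1.16, -1.18) and against lists not matched for enrichment (0.09). The HoxC cluster had a median of -0.24 over 8 promoters (percentile 21.6) and -1.25 in the value tables, with a fall at Hoxc10 (-1.14), values of -0.64 at Hoxc11, 0.10 at Hoxc5 and 0.02 at Hoxc8. The HoxD cluster had a median of -0.11 over 9 promoters (percentile 58.9), 0.09 after loess and -1.33 in the value tables, with a fall at Hoxd1 (-1.10) and values of -0.98 at Hoxd4, 0.45 at Hoxd9 and 0.47 at Evx2. The HoxD median was -0.69 with the window highest in wild type (percentile 4.49) and -0.45 with the mean over all probes (5.2).

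Over all 33 Hox promoters, 5 fell and 1 rose, and the median was -0.11, with 0.05 after loess and -1.25 in the value tables. This list lay above the central range on array design 1 alone (percentile 99.9, median 0.33) and with the window highest in Phc2 L307R (97.7, 0.25). Array design 1 carries the HoxA and HoxD promoters and array design 2 the HoxB and HoxC promoters. A single design thus holds other Hox genes and is no repeat, and HoxA and HoxB were measured on different arrays. Anterior Hox genes had a median of -0.30 over 10 promoters, which was -1.84 in the value tables at the percentile 0.89. The anterior list also lay below the central range with windows of 5 probes (0.62) and with the window highest in wild type (0.92), but above it on array design 1 alone (median 0.45). Middle Hox genes had 0.02 over 7 promoters, with 0.35 at Hoxa6 and -0.60 at Hoxb5, and 0.34 after normexp at the percentile 100, but -0.24 with arrays scaled to the same spread and -1.07 in the value tables. Posterior Hox genes had -0.09 over 16 promoters, 0.09 after loess and -1.27 in the value tables.

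**Figure D3:**
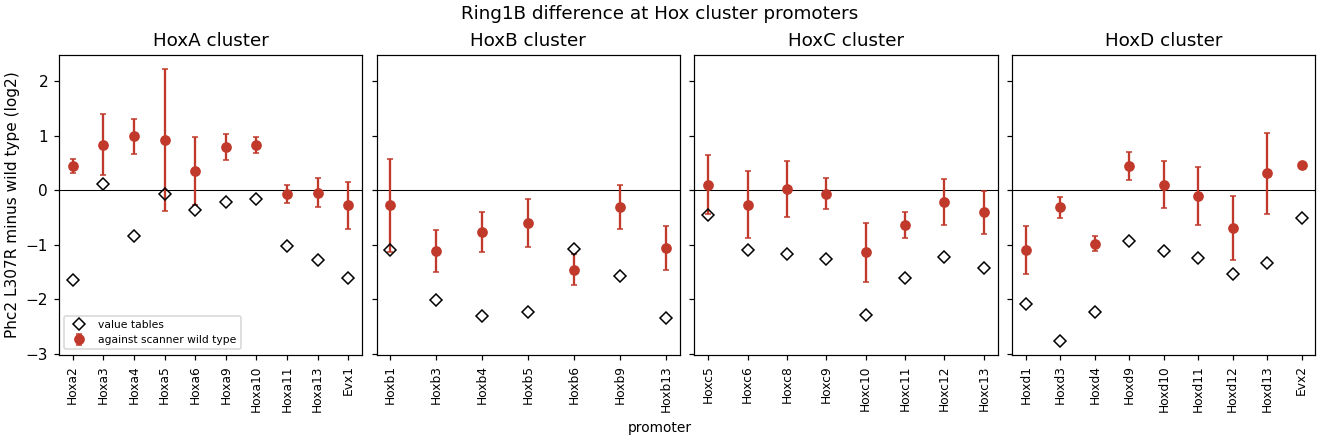
Difference in Ring1B enrichment (Phc2 L307R minus wild type, log2) at promoters of the 4 Hox clusters, against the wild-type scanner values (red circles, bars are the SD over the 3 probes of the window) and in the value tables (open diamonds). From the scanner values Hoxa4 lies at 0.99 and all 7 HoxB promoters lie below 0.

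**Figure D4:**
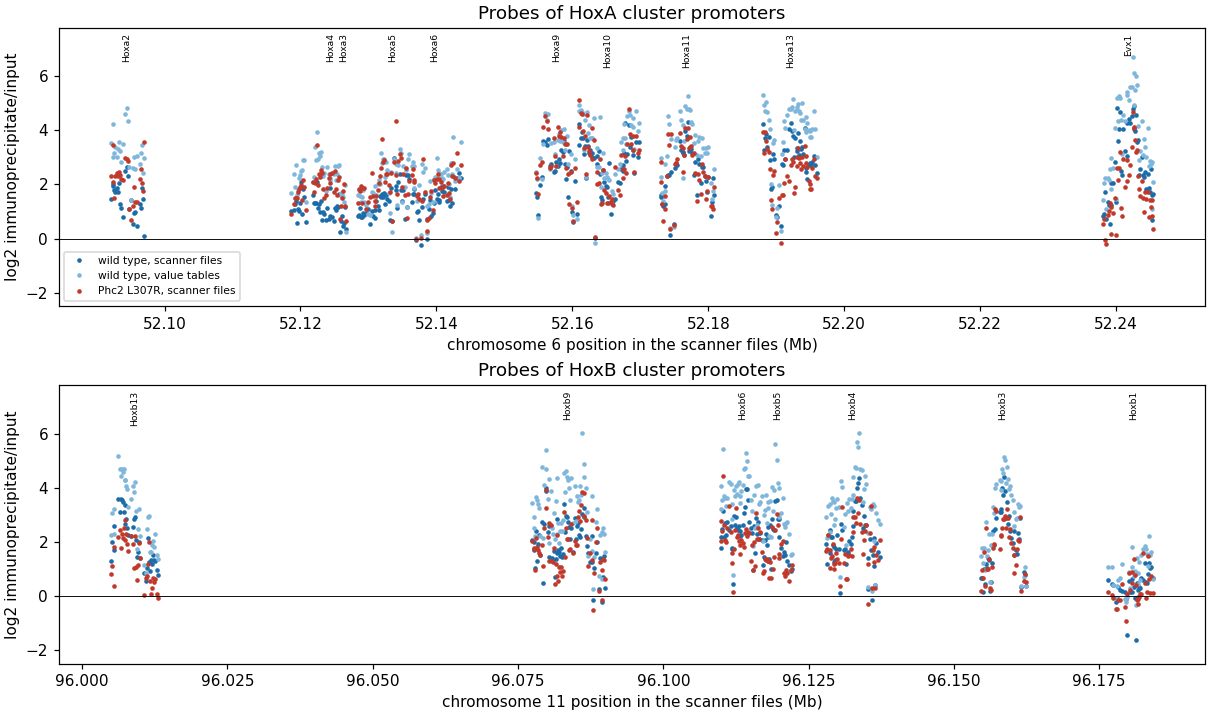
Single-probe log2 immunoprecipitate/input ratios along promoters of the HoxA cluster (chromosome 6) and the HoxB cluster (chromosome 11) at the positions of the scanner files, for wild type from the scanner files (dark blue), wild type from the value tables (light blue) and Phc2 L307R (red). At the windows used, the difference between Phc2 L307R and the wild-type scanner values was 0.99 at Hoxa4 and -1.46 at Hoxb6, and the light blue points mostly lie above the dark blue ones.

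Homeobox genes of the forebrain and the paired-like class, which pattern the neural tube and head, had lower Ring1B as a group in Phc2 L307R. The median difference was -0.45 over 47 promoters, 43 of which lay below 0, and 8 fell while 0 rose. Barhl1 (-1.86) and Gsh2 (now Gsx2, -1.64) had the largest falls, and Hlx1 (now Hlx, 0.44) and Otp (0.23) the highest differences among bound members, although these were -1.23 and -1.16 in the value tables. Gata genes, which encode zinc finger factors of blood, heart and endoderm, had a median of -0.95 over 6 promoters, with falls at Gata3 (-1.38) and Gata2 (-1.31). These were the 2 lists below the central 95% of random lists of like enrichment, at percentiles of 0.2 and 0.55, and they stayed below it in the value tables at 0.94 and 2.29, with medians of -1.66 and -2.09. The value tables share the Phc2 L307R arrays. In simulated arrays with probe noise only and no list changed, 3 of 39 lists lay outside the central 95% on either side. Between the 2 sets of wild-type values the forebrain and Gata lists lay inside it (percentiles 5.83 and 41.3). Above it there were mesodermal bHLH (98.7), olfactory receptor (100) and epithelial genes (99.9), and Wnt (99.8), Fgf (99.4) and Bmp, Gdf and hedgehog ligands (99.25). Ribosomal protein genes lay below it (0.15). Such percentiles thus also arose between sets labelled as wild type. The Gata median moved inside the central range with the mean over all probes of a promoter (percentile 10.4, median -0.30). It also did so after normexp (2.90) and on array design 2 alone (3.44), where the medians of -0.99 and -0.92 were close to the -0.95 above, as did the forebrain and paired-like median on array design 1 alone (3.45, median -0.43).

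Genes of the Irx family and of the family of Six2 had a median of -0.43 over 11 promoters, with falls at Six2 and Irx6 (-1.23), falls at Irx3 (-1.08) and Irx5 (-1.08), which are named after their values were seen, and a value of 0.43 at Six4. Dlx and Msx genes had a median of -0.47 over 8 promoters, with falls at Msx3 (-1.46) and Dlx4 (-1.38) and 0.14 at Dlx2. Both lay inside the central range of random lists (percentiles 7.24 and 12.3) and below it in the value tables (1.83 and 2.01, medians -1.90 and -2.02). The first of these lists also lay below it with arrays scaled to the same spread (0.34, median -0.89), on array design 1 alone (median -1.08) and with the window highest in Phc2 L307R (2.32, -0.39).

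For the remaining transcription factor families no list lay outside the central range in the scanner values as processed by the scanner software. Pax genes had a median of -0.40 over 9 promoters, from -0.95 at Pax4 and Pax5 to 0.52 at Pax9 and 0.35 at Pax2, and -1.68 in the value tables, where Pax9 stood at -1.27 and Pax2 at -1.32. LIM homeobox genes had -0.36 over 10, with -0.89 at Lhx6, -0.79 at Isl2, 0.33 at Isl1 and 0.97 at Lhx9, and -1.61 in the value tables, where Lhx9 stood at -1.12. Nkx genes had -0.09 over 12, with falls at Nkx6-2 and at the cardiac gene Nkx2-5 (-1.47), 0.08 after loess and -1.59 in the value tables. Fox genes had -0.30 over 22, with 0 lower or higher, between -0.92 at Foxb2 and 0.75 at Foxc1 among bound members, and -1.17 in the value tables. T-box genes had -0.33 over 14, with a fall at Tbx2 (-1.07), a rise at Tbx6 and 0.76 at Tbx18, and -1.27 in the value tables. Sox genes had -0.01 over 15, with 0.63 at Sox17 and 0.60 at Sox2, 0.12 after loess and -0.75 in the value tables, where Sox17 stood at -0.75 and Sox2 at -0.71.

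Neural bHLH genes had a median of -0.18 over 19 promoters (-0.87 at Olig3, 0.59 at Bhlhb5, now Bhlhe22) and mesodermal bHLH and myogenic genes -0.23 over 15 (-0.69 at Tcf15, 0.33 at Twist1). In the value tables these were -1.02 and -0.72, below the central range at percentiles of 2.08 and 0.4, as were neural bHLH genes with the window highest in wild type (1.49). The wild-type value tables exceeded the wild-type scanner values at these 2 lists by medians of 0.85 and 0.57 (percentiles 91.8 and 98.7). POU and neuronal zinc finger genes had 0.00 over 20, with falls at Onecut1 (-1.02) and Gfi1 (-1.01), and 0.90 at Gli1, and 0.0430 with only probes well above background at the percentile 99.2, but -0.26 after normexp, -0.16 with arrays scaled to the same spread and -1.10 in the value tables.

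Genes of secreted signals had list medians near 0 in the scanner values. Wnt ligands had a median of 0.03 over 19 promoters, but -0.16 both after normexp and with arrays scaled to the same spread. Wnt11 rose (1.24, SD 1.40), with -0.49 in the value tables, -0.16 after normexp, -0.11 with only probes well above background and -0.0314 in the mean over all probes. Fgf ligands had -0.04 over 21, from -0.99 at Fgf15 to 0.95 at Fgf7, and Bmp, Gdf and hedgehog ligands -0.02 over 25 (0.03 after loess), with falls at Gdf7 (-1.21) and Nodal (-1.15) and 0.95 at Gdf5, although Nodal stood at 0.31 in the window highest in Phc2 L307R. In the value tables these medians were -0.33, -0.50 and -0.43, the last 2 below the central range at percentiles of 0.5 and 0.75. The wild-type value tables exceeded the wild-type scanner values at these lists by medians of 0.44, 0.50 and 0.39 (percentiles 99.8, 99.4 and 99.25). Differences of like size thus also stood between 2 sets labelled as wild type.

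Cdkn2a, which encodes the cell cycle inhibitor Ink4a and the p53 activator Arf and is a known Polycomb target in fibroblasts, had a ratio of 1.59 in wild type and 2.54 in Phc2 L307R at chromosome 4 (88763390 to 88764192). The difference of 0.95 (SD 0.29) did not reach the size rule and was -0.61 in the value tables. Cdkn2c (0.89), Cdkn2d (-0.97) and Cdkn1b (-0.09) were other members of the list of Cdk inhibitors, whose median was 0.01 over 6 promoters, and 0.36 with only probes well above background at the percentile 99.7, but -0.12 after loess, -0.14 with arrays scaled to the same spread and -0.17 in the value tables. Cdkn2b was not analysed here.

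Among the genes of Polycomb complexes themselves, Cbx2 fell by 1.10, from 3.35 to 2.25, and Cbx6 (-0.72), Cbx7 (0.61) and Scml2 (0.74) did not reach the rule. PRC1 subunit genes had a median of -0.17 over 20 promoters (percentile 29.8, and 2.49 on array design 2 alone), with 1 lower and 0 higher. Rnf2, which encodes Ring1B, had a ratio of 0.98 in wild type and 1.09 in Phc2 L307R, a difference of 0.12. PRC2 subunit genes had a median of 0.29 over 10 promoters (percentile 98.9), with 0.80 at Rbbp7 and 0.72 at Rbbp4 and 0 lower or higher, but -0.30 after normexp (percentile 29.7) and 0.08 in the value tables (92.7). The list also lay inside the central range after loess (96.4), with arrays scaled to the same spread (96.8), with only probes well above background (53.9), with windows of 5 probes (62.5), with windows chosen in wild type (33.8) or in Phc2 L307R (93.2), and on array design 2 alone (77.3).

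Fibroblast and extracellular matrix genes, active in these cells, had a median of 0.26 over 25 promoters at the percentile 99.8, with 0 lower or higher by the rule. The highest differences were at Fbln2 (0.99), a matrix glycoprotein gene, and Postn (0.91), which encodes periostin, and the lowest at Thy1 (-0.37). The list moved inside the central range in the value tables (0.02, percentile 97.1), after normexp (-0.18, 73.1), on array design 1 alone (95.4) and with the window highest in wild type (70.6). Ribosomal protein genes had a median of 0.03 over 75 promoters at the percentile 99.2 and 0.16 at 100 in the value tables, with 0.94 at Rps27l and -0.70 at Rpl8, but -0.08 with arrays scaled to the same spread and -0.06 after normexp, at percentiles of 98.2 and 100. For this list the wild-type value tables differed from the wild-type scanner values by a median of -0.13 (percentile 0.15). That list moved inside the central range on array design 1 alone (40.8), with the mean over all probes (57.2) and with the window highest in Phc2 L307R (95.2). Housekeeping genes had -0.20 over 24, with 0.51 at Actb and -0.59 at Gusb, and -0.06 in the value tables. Cell cycle and DNA replication genes had -0.12 over 35, with a fall at Ccnd2 (-1.15) and a rise at Rrm2 (1.23), and -0.04 in the value tables, but 0.0593 with only probes well above background, above the central range. The rise at Rrm2 did not meet the rule in the value tables (0.69) and turned to -0.27 with the window highest in wild type.

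Marker genes of other lineages showed no list outside the central range in the scanner values as processed by the scanner software apart from the olfactory receptor genes (percentile 100). Germline genes had a median of 0.10 over 27 promoters, with 0.83 at Stag3 and 0.69 at Taf7l, -0.02 after normexp and -0.07 in the value tables. Neuronal function genes had 0.09 over 22 (percentile 91.2), with falls at Slc32a1 and Gad1 (-1.37, SD 1.01) and a rise at Syn1 (1.07). The rise at Syn1 did not meet the rule in the value tables (0.63) and turned to -0.11 when only probes well above background were kept. The list median was -0.05 after normexp, -0.09 with arrays scaled to the same spread and -0.25 in the value tables. Epithelial genes had -0.07 over 16, with a fall at Cldn3 (-1.01) and -0.86 at Rbm35a (now Esrp1), but -0.80 in the value tables at the percentile 0, and -0.68 on array design 1 alone at 1.28. At the epithelial list the wild-type value tables exceeded the wild-type scanner values by a median of 0.72 (percentile 99.9). Blood cell genes had 0.18 over 17 (-0.72 at Tal1; percentile 98.5 on array design 1 alone and 99.0 with the window highest in wild type), endothelial genes -0.14 over 10 (-0.40 at Flt1), liver genes -0.05 over 12 with 0 bound, and skeletal and heart muscle genes 0.09 over 19 (-0.08 after normexp), with 0.99 at Tnnt2, whose value-table difference was 1.64. In the value tables these medians were 0.12, -0.05, 0.12 and -0.09.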

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

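The test of probes without a gene name was chosen after the results were seen. Of 431 regions covered only by such probes, over 10842 probes, 6 had a window at or above 3 (log2) in wild type and 7 in Phc2 L307R, against 0 with a lowest window at or under -3 in wild type. At a cut-off of 1, 119 regions were bound in wild type and 5 reached the opposite value. These regions stand outside the comparisons of promoters, which use named probes, and no explanation was tested.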

How the results depend on the processing

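The bound cut-off of 3 and the comparison against both sets of wild-type values were chosen after the results were seen; all other settings were fixed before. No paired analysis was possible because the title numbers name array designs without shared probes and each promoter has 1 array per genotype. The median difference stayed below 0 under every setting except the window highest in Phc2 L307R. Where a cause is not given, the cause was not tested. Input signal was well above background at 75.0% to 86.7% of probes, which limits ratios of dim probes.

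Normexp gave 4033 bound promoters in wild type and 2252 in Phc2 L307R, a share of 48.0%, 11 higher and a median of -0.34; PRC2 subunit genes stood at -0.30, fibroblast genes at -0.18, ribosomal protein genes at -0.0582, Wnt11 at -0.16, Sulf1 at -0.17 and Tbx6 at -0.0546. Scaling to the same spread gave a share of 69.9%, 418 lower, a median of -0.27, 4 lists below the central range against 2, and ribosomal protein genes at -0.0843. The value tables gave a share of 76.5%, 731 lower, 52 higher, 10 lists below, HoxA at -0.37 and Wnt11 at -0.49. Against both sets of wild-type values 103 were lower and 27 higher, fewer by construction.

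With only probes well above background the share was 68.3%, with 147 lower, 32 higher and a median of -0.21; PRC2 subunit genes stood at -0.0865, ribosomal protein genes at -0.0472, Syn1 at -0.11, Wnt11 at -0.11, Sulf1 at -0.21, Tbc1d12 at -0.0619 and Tbx6 at -0.31. Windows of 5 probes gave a share of 71.1%, 107 lower, 47 higher, PRC2 subunit genes at -0.0278 and ribosomal protein genes at -0.0210. The mean over all probes gave 833 and 704 bound, a share of 72.3%, 12 lower, 2 higher, 1 list below, 19 lists with a wild-type median at the cut-off against 32, ribosomal protein genes at -0.0518 and Wnt11 at -0.0314.

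Choosing the window in a single genotype favours that genotype by construction. In wild type it gave a share of 65.9%, 467 lower, 32 higher, a median of -0.30 and 4 lists below, with PRC2 subunit genes at -0.27, fibroblast genes at -0.16, ribosomal protein genes at -0.0872, Rrm2 at -0.27, Gimap4 at -0.0024, Sulf1 at -0.42, Tbc1d12 at -0.11, Olfr456 at -0.20 and Tbx6 at -0.17. In Phc2 L307R it gave a share of 82.8%, 90 lower, 295 higher and a median of 0.0397, with Hoxb6 at 0.55 and Nodal at 0.31.

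A bound cut-off of 1.5 gave 3874 and 3277 bound, a share of 64.3% and 92 higher. A cut-off of 3 gave 278 and 255 bound, a share of 69.4%, 59 lower, 13 higher, a median of -0.30 and 11 lists at the cut-off. Array design 1 alone gave a share of 71.8%, 179 lower, 76 higher and ribosomal protein genes at -0.14, and design 2 alone 76.8%, 92 lower and 72 higher, with fewer promoters by construction. A size rule of 1.5-fold gave 1209 lower and 576 higher. Counting each distinct window once changed nothing by construction.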

Other observations

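The tests of explanations for the 3 patterns below and the look at mitochondrial probes were chosen after the results were seen, whereas the gene lists, their random lists and the normexp, loess and scaling settings were fixed before. The lists with a higher median than the central range of random lists, but with no member called higher or lower, were PRC2 subunit genes (0.29), fibroblast and extracellular matrix genes (0.26) and ribosomal protein genes (0.03), and after normexp they lay at -0.30, -0.18 and -0.06. Mitochondrial probes ranged from -1.99 to -0.39 in wild type and from -5.19 to -3.26 in Phc2 L307R over 47 probes, so the ranges did not overlap. All 47 were on array design 2, so they compare 1 array per genotype and say nothing of array design 1. Whether input or immunoprecipitated DNA was prepared alike for both genotypes was not tested.

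HoxA promoters held more Ring1B in Phc2 L307R relative to promoters of like enrichment, with a median difference of 0.79 from the scanner values and -0.37 in the value tables, at a percentile of at least 99.8 under every setting run. The other bound cut-offs, the other size rule and array design 1 alone cannot change this median. All settings also use the same Phc2 L307R array, so they are no independent repeats. HoxA promoters lie side by side, unlike the members of the random lists, so the percentile may overstate how unusual they are. The HoxA median exceeded that of the HoxD cluster on the same slides by 0.90, more than the combined half-width of their random lists. This argues against a difference between the slides of array design 1 that acts alike on both clusters. Centring had already removed a shift of a whole slide, and a slide difference local to the HoxA probes was not tested. Less input signal is argued against by an input difference of -0.12 (random lists -0.31 to 0.11), beside 0.72 in the immunoprecipitate. The genotype, the scan day and the embryo or body position from which the fibroblasts came stay open and may each contribute.

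The wild-type value tables differ from the wild-type scanner arrays. Another normalization of the same arrays is argued against by the correlation of the table with its best fit from that array's ratio and brightness, 0.908 at most, where the Phc2 L307R tables reached 0.991 and 0.992. Another array of wild-type chromatin remains a candidate explanation. The tables correlated better with the wild-type than with the Phc2 L307R arrays by 0.0335 and 0.0567, but successive-probe differences in silent regions correlated better with Phc2 L307R (0.494 and 0.546) than with wild type (0.469 and 0.517), so wild-type chromatin and another origin of the tables cannot be told apart by these values.

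Promoters at or above 3 held less Ring1B in Phc2 L307R, with a median difference of -0.30. A narrower range of all ratios on the Phc2 L307R arrays stays open, since the spread shared by neighbouring probes was 0.933 and 0.941 of that in wild type. That spread leaves out probe noise, whereas the median absolute deviation, another measure that includes noise, was 1.05 and 1.11 of that in wild type. Without these promoters and after loess the shared spread was 0.984 and 0.998 (the latter with a 95% interval reaching 1.00), and less Ring1B at many promoters would narrow it too. A trend with brightness within arrays stays open, since loess left -0.0544, and loess may also remove real differences where bright probes are the bound ones. Differences between arrays of the same genotype stay open too, since the sets of wild-type values differed by a median of 1.17 at such promoters.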
